A study of Glycine max with 10 samples.

How the data were processed

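RNA from pods of 10 soybeans (Glycine max), taken 18 days after flowering from field-grown plants, was sequenced as paired-end libraries made with a TruSeq RNA kit, per the labels' protocols. The labels place 5 soybeans in a group with high pod shattering force (015, 018, 044, 060 and 071) and 5 in a group with low pod shattering force (038, 055, 072, 092 and 109), named high_force and low_force here. The groups share no soybean number, so no pairing was used. The labels do not say whether a numbered soybean is a single plant, a line or a pool, so p-values measure the spread between these 10 samples only. They also do not say how the force was measured or which group shatters more readily in the field.

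The authors deposited raw read counts per gene, as whole numbers, for 56044 genes in 10 libraries. The submitters' processing notes name Trim Galore 0.4.4, TopHat2, featureCounts, Subread 1.6.2 and edgeR, with no role, order or setting for any of them. The genome build is not given in the sources used here, apart from the Wm82.a2.v1 ending of the gene IDs. Strand handling and the treatment of reads that match several genes are also not given, so counts of near-identical gene copies are uncertain.

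Library totals ran from 3779756 (high_force 018) to 13298201 counts (high_force 044). A count of 0 allows up to 3 counts, which is 0.149 CPM (counts scaled to a library size common to all libraries) in high_force 044 and 3.26 CPM in low_force 055, the library with the smallest depth after normalisation. These limits cover counting error only. No pair of libraries agreed within sampling noise (smallest chi-square per degree of freedom 10.9), so none was treated as a repeat of another library. This does not show that the samples are independent.

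Counts were normalised by the trimmed mean of M-values (TMM) and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with low-count genes removed by filterByExpr, which left 30226 genes. The log2 fold change is high_force minus low_force. The standard error (SE) is the log2 fold change divided by the square root of F. Adjusted p is Benjamini-Hochberg over all genes tested, with a threshold of 0.05, two-sided. CPM values are TMM-normalised, and log2 CPM uses a prior count of 2. Single genes and library measures were also compared with two-sided exact permutation tests over the 252 assignments of 10 libraries to groups of 5, whose smallest possible p is 0.00794. Principal components used the 500 most variable genes. Gene classes with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry, in limma 3.58.1 and edgeR. Neighbouring genes with small p were counted in windows of 30 tested genes against 10000 random draws, one-sided.

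The test was checked on simulated counts for the same 30226 genes in 5 against 5 libraries, with 200 genes changed. Each gene was drawn on its own around a level common to both groups, so differences that many genes of a library share are missing. The rates hold for such counts and may differ in the real libraries. On the simulated counts, edgeR's quasi-likelihood test recovered 2% of genes changed 2-fold, 44% at 4-fold, 96% at 8-fold and 96% at 16-fold, with 5 false calls among 124. DESeq2 recovered 8%, 68%, 98% and 98%, with 47 false calls among 183. The edgeR exact test recovered 6%, 62%, 98% and 98%, with 36 false calls among 168, and limma-voom recovered 2%, 46%, 86% and 90%, with 5 false calls among 117.

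The groups, tests, other settings and the rule for named genes were fixed before the data were examined. The rule names genes past the threshold with separated groups and a gene description. If fewer than 10 pass, it names those with the smallest p, with at most 2 IDs in each direction where no description can be matched, and it always names a list of 19 published genes. The gene table used for names (assembly Glycine_max_v4.0) holds 59048 genes and matched 0 of the IDs, so the 35 gene lists planned from descriptions were not run. Gene names were instead paired with IDs from published work on soybean, as recalled, and not from the files. A further 25 genes (seed reserve, seed oil, sugar transport, clock and flavonoid genes) were added after library totals and the most abundant genes had been seen but before any test between the groups. Gy1, Gy4 and CG-alpha-prime were by then known to be abundant in low_force 109, so the seed reserve class was not chosen blind. Since no gene passed over all genes tested, the position test, planned for called genes, was run on genes with unadjusted p under 0.01.

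The other settings fixed at that time were relative log expression and upper-quartile scaling, library size only, no filter, at least 1 CPM in 5 libraries, DESeq2 1.42.0, the edgeR exact test, limma-voom with and without quality weights, robust quasi-likelihood, a surrogate variable from sva 3.50.0, and leaving out each soybean. Alternatives chosen after seeing the data were DESeq2 at its default filtering level, the mean LHY level as covariate, leaving out low_force 055 and 109 together, leaving out low_force 055 with the LHY covariate, the 7 libraries with low LHY, removal of a block of chromosome 13 IDs, and gene classes in place of description lists. A permutation test of Pdh1 without low_force 055 was also run but is not used here, since leaving out the library that overlapped the other group fixes its outcome.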

Results

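The transcriptomes of pods from 5 soybeans with high and 5 with low pod shattering force were compared 18 days after flowering, to find genes whose expression differs with pod dehiscence. Totals were 5140148, 3779756, 13298201, 4016401 and 9150000 counts for high_force 015, 018, 044, 060 and 071, and 7373524, 6528403, 5014711, 8638848 and 7908467 counts for low_force 038, 055, 072, 092 and 109. A count was seen for 41462 genes in high_force 044 and for 30465 in low_force 055, the most and the fewest of the 10 libraries.

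Pdh1 (Glyma.16G141400), a dirigent-like gene known as a quantitative trait locus for pod dehiscence, was lower in high_force pods. Its level was 0.857 ± 0.781 CPM in high_force (SD, n = 5) and 10.8 ± 10.2 CPM in low_force (SD, n = 5), a log2 fold change of -3.82 (SE 0.81). High_force libraries lay between 0.398 and 2.25 CPM, on 3 to 12 counts each, so their levels are uncertain. Low_force 038, 072, 092 and 109 lay at 5.11, 5.75, 20.8 and 22.6 CPM, while low_force 055 had 0 counts at a depth that allows up to 3.26 CPM. SHAT1-5 (Glyma.16G019400) and NST1A (Glyma.07G050600), which encode NAC factors linked to secondary walls of the pod, stood at similar levels in both groups. SHAT1-5 was at 22.9 ± 3.49 CPM in high_force and 22.9 ± 5.63 CPM in low_force, and NST1A at 39.9 ± 6.85 and 33.8 ± 7.25 CPM (SD, n = 5 each).

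Of these 3 shattering genes, Pdh1 passed edgeR's quasi-likelihood test adjusted over the list alone (adjusted p = 0.00142) and none passed over all genes tested (Pdh1 adjusted p = 0.796, the fourth smallest p). NST1A had a log2 fold change of 0.24 (SE 0.22, adjusted p = 0.458 over the list alone) and SHAT1-5 one of -0.01 (SE 0.23, adjusted p = 0.954), whose sign turned with library size scaling (0.49). In the two-sided exact permutation test Pdh1 did not pass (p = 0.111, adjusted 0.286 over the 3 genes), with low_force 055 at 0 counts. At the level of low_force 038 that library would give 4.71 Pdh1 counts, and counting error alone would then give 0 counts with a chance of 0.903%.

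**Figure D1:**
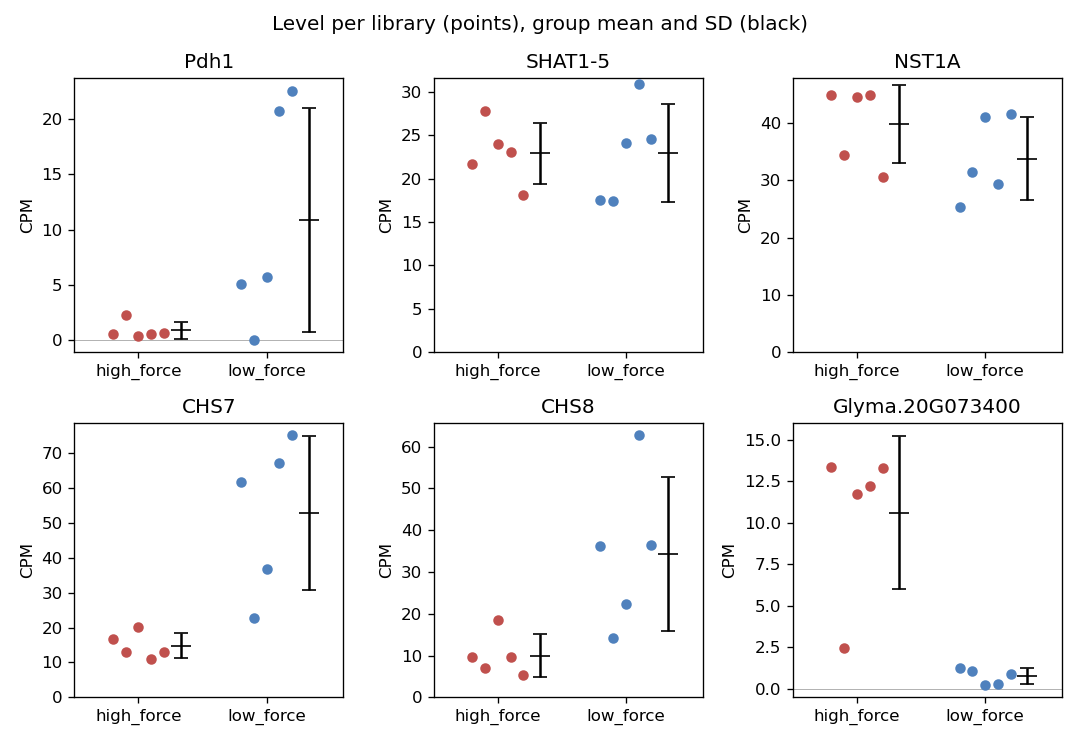
Levels in CPM of 6 genes (vertical axes) in high_force and low_force pods, with each point a library and the black bar the group mean with its SD (n = 5). Pdh1 lies at or below 2.25 CPM in high_force and between 0 and 22.6 CPM in low_force, CHS7 does not overlap between the groups, and SHAT1-5 and NST1A overlap.

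The 2 chalcone synthase genes on the added list, CHS7 and CHS8, which encode the entry enzyme of flavonoid synthesis, had lower levels in high_force pods. Other chalcone synthase genes were not looked up. CHS7 (Glyma.01G228700) was at 14.8 ± 3.60 CPM in high_force and 52.7 ± 22.1 CPM in low_force (SD, n = 5 each), with every high_force library below every low_force library, of which low_force 055, the lowest, rests on 21 counts. CHS8 (Glyma.11G011500) was at 10.01 ± 5.14 and 34.4 ± 18.5 CPM. The log2 fold changes were -1.85 (SE 0.33) for CHS7 and -1.79 (SE 0.42) for CHS8. The flavonoid 3'-hydroxylase of the T locus (Glyma.06G202300) stood at 21.6 ± 14.3 and 28.4 ± 21.3 CPM, with no difference past the threshold.

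Of the 25 added genes 15 were tested by edgeR's quasi-likelihood test, and CHS7 and CHS8 passed adjusted over the list alone (adjusted p = 0.00138 and 0.00808) but not over all genes tested (adjusted p = 0.796 for both). This list was written after the most abundant genes had been seen, and the flavonoid class, with 3 tested members, was too small for a class test. The exact permutation p was 0.00794 for CHS7, the smallest possible, and 0.0159 for CHS8 (0.119 for both after adjustment over the 15 genes). CHS7 and CHS8 are near-identical copies that can share reads, so their separate levels are uncertain.

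Genes of flowering, isoflavone synthesis and common reference use did not pass. The florigen genes FT2a (Glyma.16G150700) and FT5a (Glyma.16G044100) had log2 fold changes of -1.19 (SE 0.64) and -1.17 (SE 0.54), and the isoflavone synthase genes IFS1 (Glyma.07G202300) and IFS2 (Glyma.13G173500) -2.14 (SE 0.92) and -1.14 (SE 0.73). J (Glyma.04G050200), an ELF3 gene of the evening complex, had 0.95 (SE 0.66; 0.70 without low_force 072 and 1.73 without low_force 038), with E2, E3 and E4 between 0.16 and 0.41. The reference genes ACT11, ELF1B, UKN1 and TIP41 had -0.45, -0.37, 0.0048 and -0.05, and under library size scaling ELF1B and TIP41 changed sign (0.078 and 0.44), as UKN1 did with relative log expression scaling (-0.0068). In edgeR's quasi-likelihood test 0 of the 12 tested genes of this list of 16 passed adjusted over the list alone (smallest adjusted p = 0.300), and 0 over all genes. E1 and Dt1 had 0 counts in all 10 libraries, and Dt2 and Ln had at most 3 counts in any library, too few for a comparison. With library size only, where the median of all genes moved by 0.55, FT5a had -0.57 and IFS2 -0.34. Without high_force 015, FT5a (-1.73) passed over the list alone in edgeR (adjusted p = 0.0496). In the 7 libraries with low LHY, chosen after seeing the data, FT2a (-2.32) and IFS1 (-3.14) passed over the list alone in edgeR (adjusted p = 0.00680 and 0.0163). That choice left out high_force 015, the highest of its group for both genes (32.2 and 4.79 CPM). It also left out low_force 055 and 072, the lowest of theirs (FT2a 8.68 and 7.12 CPM, IFS1 2.17 and 0.230 CPM). These passes therefore depend on which libraries were left out. Without low_force 092 FT2a and IFS1 had -0.43 and -1.09 (adjusted p = 0.490 for both in edgeR), and with the surrogate variable -0.92 and -1.68 (adjusted p = 0.306 for both).

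Seed reserve genes were abundant in low_force 109 and scarce in the other 9 libraries. The glycinin gene Gy1 (Glyma.03G163500) reached 5571 CPM in low_force 109 against at most 65.3 CPM elsewhere. The lectin gene Le1 (Glyma.02G012600) reached 437.6 CPM (4344 counts), with at most 9 counts in any other library. For 8 of the 11 genes of the class the next library lay above the limits of detection, and low_force 109 lay 41.2- to 133.7-fold above it. Genes of seed oil and sugar transport followed, with FAD2-1B (Glyma.20G111000) at 85.7 CPM and SWEET10b (Glyma.08G183500) at 32.6 CPM in that library.

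The 6 tested members, Gy1, Gy3, Gy4, Gy5, CG-alpha-prime and KTI3, each passed edgeR's quasi-likelihood test adjusted over the list alone (adjusted p = 0.0378 each) and none over all genes tested. Their log2 fold changes lay between -6.54 (Gy4) and -5.01 (Gy3). The call was lost for all 6 with the robust fit (adjusted p = 0.05004), the surrogate variable, limma-voom, and without high_force 018, 044 or 071 (adjusted p = 0.0823, 0.0799 and 0.0836). The log2 fold changes were the same in the robust fit, -6.45 to -4.56 without those soybeans, -5.44 to -4.39 with the surrogate variable and -4.47 to -2.998 with limma-voom. Two-sided exact permutation p lay between 0.270 and 0.722. Camera placed the class lower in high_force (adjusted p = 0.0203), with adjusted p = 0.830 with an estimated correlation and fry p = 0.360. Without low_force 109 the adjusted p of the class was 0.973, and the log2 fold changes of the 6 genes lay between -0.32 and 0.80. The clock and flowering classes had camera adjusted p = 0.827 each. Without high_force 015, the only library of its group with high LHY, the clock class had camera adjusted p = 0.0244.

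Over all 30226 genes tested, edgeR's quasi-likelihood test called 0 genes higher and 0 lower in high_force, and 0 at least 2-fold different (smallest adjusted p = 0.688). At unadjusted p under 0.05 there were 1893 genes, 747 higher and 1146 lower, where chance gives 1511. That excess depends on single libraries: the count was 1214 without low_force 092 (chance 1530) and 1261 without high_force 071 (chance 1527.5), and it was also below chance without high_force 018, 044 or 060 (1280, 1451 and 1390). On the same genes the edgeR exact test called 1 higher and 1 lower, and limma-voom 0. DESeq2, run on the 46734 genes with a count, called 6 higher and 19 lower, 8 of these 25 on genes that edgeR did not test. The smallest p belonged to Glyma.20G073400, at 10.6 ± 4.62 CPM in high_force and 0.760 ± 0.471 CPM in low_force (SD, n = 5 each; log2 fold change 3.84, SE 0.58). Low_force 055 had 1 count of it, so at the depth of that library it cannot be placed below high_force 018 (2.44 CPM). Glyma.06G120300 stood at 17.4 ± 3.68 and 5.71 ± 3.09 CPM (log2 fold change 1.75, SE 0.33, edgeR adjusted p = 0.796). CHS7 and Pdh1 had the smallest p among genes lower in high_force. DESeq2 called all 4 (adjusted p = 6.97e-06 for Glyma.20G073400, 0.00220 for Glyma.06G120300, 0.00132 for CHS7 and 0.00895 for Pdh1), although it made 47 false calls among 183 in the simulated comparison of 30226 genes. The groups did not overlap for 181 genes higher and 117 lower in high_force, 0.986% of those tested, where chance gives 0.794%. The biological coefficient of variation was 48.03%.

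Genes with small p lay together in one stretch of chromosome 13. Of 358 genes with unadjusted p under 0.01, 69 lay in a block of 129 consecutive IDs there, all lower in high_force. The fullest window of 30 tested genes held 26 of them (one-sided permutation p = 0.0001, the smallest the draws can give). The draws treat genes as independent, while genes of the block can vary together between libraries. This p therefore does not measure the spread between soybeans. Without the block the fullest window held 3 (permutation p = 0.9996), and 289 genes outside it had unadjusted p under 0.01 against 301 by chance. The block took 78.2% of the counts in low_force 055, 26.1% in low_force 072 and 1.33% in high_force 044. Its share was 7.43 ± 5.15% in high_force and 28.3 ± 29.0% in low_force (SD, n = 5 each; two-sided exact permutation p = 0.0714, adjusted 0.250 over 7 library measures). Without low_force 055 the low_force share was 15.8 ± 8.87% (SD, n = 4).

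Libraries differed in clock genes within both groups. LHY1a (Glyma.16G017400), a morning gene of the circadian clock, lay between 646.7 and 1041 CPM in high_force 015 and low_force 055 and 072, and between 11.8 and 19.3 CPM in the other 7 libraries. LHY1b, LHY2a and LHY2b split the same libraries, by gaps of at least 10.04-fold. PRR3b (Glyma.12G073900), another clock gene, overlapped between them, at 33.6 to 72.45 CPM in these 3 libraries and 72.35 to 156.9 CPM in the other 7. J lay between 8.96 and 14.1 CPM in these 3 libraries and between 22.0 and 114.5 CPM in the others. The difference in the mean LHY level between the groups did not pass (two-sided exact permutation p = 0.833), and it depends on high_force 015: without it LHY1a, LHY1b, LHY2a and LHY2b were lower in high_force in edgeR's quasi-likelihood test adjusted over the list alone (-4.04, -2.60, -5.71 and -6.69, adjusted p = 0.0293, 0.0431, 0.0213 and 0.0216). Leaving out the only high_force library with high LHY fixes this direction, so these p-values are no evidence of a group difference. Pdh1 had a log2 fold change of -4.24 (SE 0.69) in the 7 libraries with low LHY. These leave out low_force 055, the only low_force library that overlapped high_force for Pdh1, so the value is not separate support. The 3 libraries with high LHY hold 1 of high_force, too few for a value.

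The first principal component took 46.3% of the variance and the second 14.3%. The difference between the groups did not pass after adjustment over 7 library measures along the second (two-sided exact permutation p = 0.0159, adjusted 0.111) or the first (p = 0.286, adjusted 0.542). The median Spearman correlation across genes was 0.909 between high_force libraries, 0.808 between low_force libraries and 0.826 between the groups. The difference of 0.101 between the groups was within the range of regroupings (two-sided exact permutation p = 0.246).

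**Figure D2:**
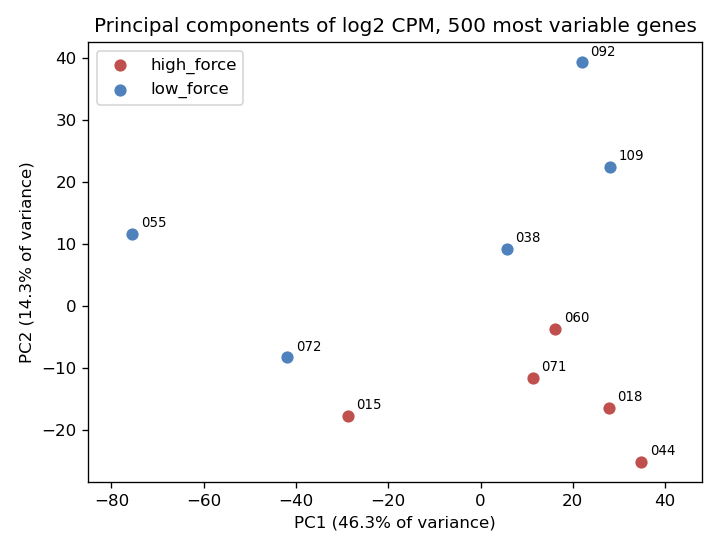
The 10 libraries on the first and second principal components of log2 CPM (axes in component units, share of variance in the labels), coloured by group and marked with the soybean number. Low_force 055 and 072 and high_force 015 lie to the left, at -75.5, -41.9 and -28.7 on the first component.

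**Figure D3:**
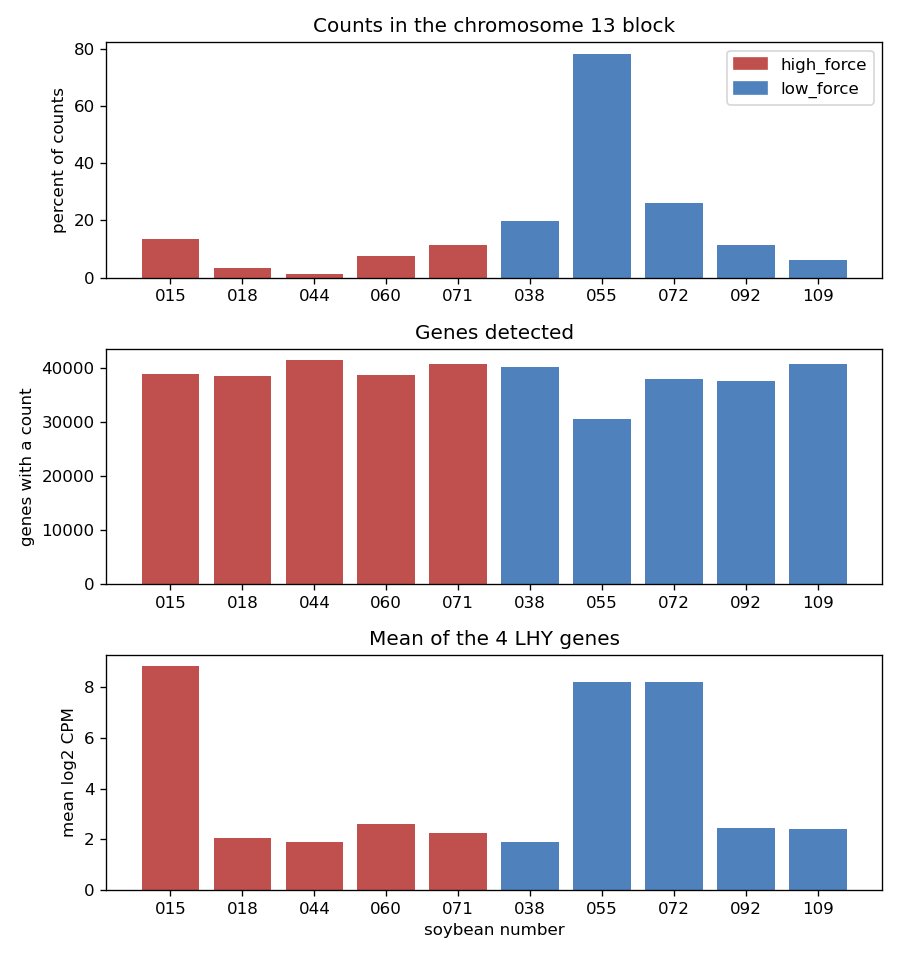
Share of counts in the chromosome 13 block (percent), number of genes with a count, and mean log2 CPM of the 4 LHY genes, with a bar for each library coloured by group. Low_force 055 has the largest block share (78.2%) and the fewest genes (30465), and high_force 015 and low_force 055 and 072 have the highest LHY means.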

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

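The tests of ribosomal RNA, of library depth and pod phenotype for LHY, and all those of Pdh1 except the count of splits, were chosen after their results had been seen. Within groups of 5, 76 sets of values (library measures and named genes) were searched for a sample far from the others, a rule by which chance picks about 1 in 20, and 12 were found.

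Soybean 015 stood apart in high_force for clock genes, with log2 CPM of 10.02 for LHY1a, 7.64 for LHY1b, 8.39 for LHY2a, 9.29 for LHY2b and 3.50 for J, and also for ELF1B (6.26). Soybean 109 stood apart in low_force for the seed storage genes Gy4 (11.25) and CG-alpha-prime (12.04). Soybean 018 stood apart in high_force for Pdh1 (1.32) and Glyma.20G073400 (1.42), and soybean 092 in low_force for UKN1 (6.10). The share of counts in the chromosome 13 block was far above the other low_force libraries in soybean 055 (78.2%).

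The LHY genes were high in high_force 015 and low_force 055 and 072. LUX1 and LUX2, evening genes chosen to test the hour of harvest, were lower (2 of 2) in these 3 libraries than in each of the other 7. The choice may not have been blind, since an exploratory fit of these 3 libraries against the other 7, not reported here, had been run. J, of the evening complex, was low in the same 3 libraries, so low LUX may not be separate evidence. LUX1 lay between 0 and 3.26 CPM against 24.4 to 44.2 CPM, and LUX2 between 1.38 and 8.68 CPM against 32.1 to 69.8 CPM. Pod phenotype is argued against by 1 of the 3 libraries being from high_force, with 3 low_force libraries among those with low LHY. Low depth is argued against: in these 3 libraries each of the 4 LHY genes lay at least 10.04-fold above its highest level in the other 7. Their lowest level there, 104.3 CPM for LHY1b, is far above the 3.26 CPM that 3 counts make in low_force 055. Low_force 055 and 072 have the smallest effective depths of the 10 (0.922 M and 4.35 M counts). That of high_force 015 (6.06 M) exceeds the 5.34 M and 5.33 M of high_force 018 and 060, which had low LHY. The order of effective depths, the test chosen for this, therefore does not decide by itself. A difference in the hour of harvest is a candidate explanation, as a hypothesis, since the labels give no hour.

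Fewer genes were detected in low_force 055 than in any other library, and the chromosome 13 block took most of its counts. Depth left outside the block was tested by thinning the other 9 libraries to the same count (1421180). They still detected at least 33469 genes outside the block, against 30344 in low_force 055. That count alone does not account for the low number. Depth stays open, since the thinning did not match the effective depth of low_force 055 (0.922 M). The 10 most abundant genes took 85.8% of its counts, more than the block. Ribosomal RNA carried into the library may account for the block, as 88.5% of the rRNA genes in the gene table lie on chromosome 13. This cannot be told apart from another source, because none of the block's IDs matched that table. No biological explanation was tested.

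Pdh1 was lower in high_force. With the LHY level as covariate the log2 fold change of Pdh1 was -3.99 (SE 0.73), so the split in LHY level does not account for it. The hour of harvest stays open, since LHY splits the libraries 3 against 7 and cannot mark different hours among the 7. The log2 fold change did not rest on a single library, with values no higher than -3.38 when each soybean was left out. This covers its size only: the two-sided exact permutation test did not pass (p = 0.111) with low_force 055 at 0 counts. A linked segment of chromosome 16 cannot be told apart, since 4 of the 30 neighbouring genes reached unadjusted p under 0.05 where 1.88 would by chance (one-sided exact binomial p = 0.115). Chance was not excluded: 8 of 100 splits of the 10 libraries into 5 and 5, the real one included, gave as many as 1 shattering gene past the threshold adjusted over the list alone (highest of the others 1). The pod phenotype and the genetic background of these soybeans stay open.

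Other counts were set against the same 100 splits. For the 0 genes called by edgeR's quasi-likelihood test the count decides nothing, since all 100 splits must give as many (highest of the others 6; 1893 genes at unadjusted p under 0.05, 25 calls by DESeq2). Chance was not excluded for the 1893 genes at unadjusted p under 0.05 (25 splits, highest 4579; 1214 genes without low_force 092), or for the 8 added genes past the threshold over the list alone (22 splits, highest 14). The split with 6 calls set high_force 015 and low_force 055, 072, 092 and 109 against the rest. It was the 1 with a call among the 16 splits that keep the 3 libraries with high LHY together, and 8 of the other 84 splits had a call.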

How the results depend on the processing

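The alternatives named as added in the processing summary were chosen after seeing the data. Pdh1 stayed lower in high_force and past the threshold over the list alone in every alternative fit run. Its log2 fold change lay between -4.47 and -3.38 when each soybean was left out. CHS7 also stayed lower and past that threshold when each was left out (-2.03 to -1.69). The two-sided exact permutation test of Pdh1 did not pass (p = 0.111, adjusted 0.286 over the 3 shattering genes). Genes called, 0 in the main test, numbered 62 with library size only (36 higher, 26 lower; the median of all genes moved by 0.55), 25 with DESeq2, 14 with DESeq2 at its default filtering level (2 higher, 12 lower), 2 with the exact test, 1 without low_force 055 and 109, 2 without 055 with the LHY covariate, and 2 in the 7 libraries with low LHY, the same numbers at 2-fold. They were 0 with the other scalings, filters, voom fits, the robust fit, the surrogate variable, the LHY covariate and the block removed. With each soybean left out they ran from 0 to 1 (1 without high_force 015, high_force 071 or low_force 055), and the shattering genes that passed stayed at 1. The seed reserve class had adjusted p = 0.830 with an estimated correlation and 0.777 with fry, and 0.000231 to 0.973 with each soybean left out, the last without low_force 109. The 6 tested genes of the class each passed over the list alone with the other scalings, filters and the exact test, and 0 of 6 passed with the robust fit, voom with or without weights, the surrogate variable, the LHY covariate (with or without 055), without 055 and 109, or without high_force 018, 044 or 071 or low_force 109 (2 of 6 without high_force 015). DESeq2 gave these 6 genes no p. The clock class ran from 0.0244 (without high_force 015) to 0.985 and turned direction without high_force 018 or 044 or low_force 055 or 072. The flowering class ran from 0.552 to 0.988 and turned direction with library size only (0.831) and without high_force 015 or low_force 072 or 109. The fullest window held 2 genes for DESeq2's calls and 3 with the block removed.

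Some log2 fold changes turned sign. UKN1 (0.0048) had -0.0068 with relative log expression, -0.013 with DESeq2 at either filtering level, -0.0013 with the exact test, -0.0043 with voom, -0.011 with the surrogate variable, -0.0018 with the LHY covariate, -0.13 without 055 and 109, -0.068 without 055 with the LHY covariate, -0.14 in the 7 libraries and -0.0028 with the block removed. With library size only, SHAT1-5 had 0.49, ELF1B 0.078, TIP41 0.44, LHY1a 0.92, LHY1b 1.05, LHY2a 0.51 and LHY2b 0.85. SHAT1-5 had 0.0083 with no filter and 0.088 with quality weights. LHY1b had 0.12 with the surrogate variable and 0.26 without 055 and 109, where Gy1 had 0.039, Gy4 0.057 and KTI3 0.68. LHY1a and LHY1b had 0.26 and 0.25 with the LHY covariate, 0.28 and 0.29 without 055 with that covariate, and 0.30 and 0.20 in the 7 libraries, where LHY2b had 0.11. With each soybean left out, the ranges were -0.10 to 0.12 for SHAT1-5, -0.071 to 0.17 for UKN1, -0.13 to 0.042 for TIP41, -7.48 to 0.28 for Gy1, -7.85 to 0.28 for Gy4, -8.16 to 0.17 for CG-alpha-prime, -7.08 to 0.80 for KTI3, -4.04 to 0.38 for LHY1a, -2.60 to 0.57 for LHY1b, -5.71 to 0.52 for LHY2a, -6.69 to 0.30 for LHY2b and -0.89 to 0.13 (without low_force 092) for the T locus gene, whose main value was -0.42. FT5a passed over the list alone without high_force 015 (-1.73, edgeR adjusted p = 0.0496), as did the 4 LHY genes (adjusted p 0.0213 to 0.0431). For the LHY genes this follows from leaving out the only high_force library with high LHY. SACPD-C had -1.90 in the main test and did not pass (edgeR adjusted p = 0.103 over the list alone). It passed with library size only (adjusted p = 0.0256), without low_force 072 (0.0237) and in the 7 libraries (0.0331). With each soybean left out its log2 fold change ran from -2.28 to -0.25. The number of genes at unadjusted p under 0.05 ran from 1214 (without low_force 092) to 2689 (without high_force 015) with each soybean left out. The cause was not tested. Depth limits low_force 055 most, where 0 counts allow 3.26 CPM.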

Other observations

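Seed genes outside the reserve class were also highest in low_force 109. FAD2-1A (Glyma.10G278000), a seed oleate desaturase gene, was at 18.2 CPM there and at 0 counts in low_force 038, 055, 072 and 092. The stearoyl desaturase gene SACPD-C (Glyma.14G121400) was at 69.3 CPM in low_force 109 and 11.1 CPM in low_force 038, and SWEET10a (Glyma.15G049200), a seed sugar transporter gene, at 2.82 CPM there and at 0 counts in low_force 038. No hypothesis on its cause was tested.

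The flavonoid 3',5'-hydroxylase gene of the W1 locus (Glyma.13G072100), which acts in purple flower pigment, was at 11.5 CPM in low_force 092 and at most 1.32 CPM in high_force, with 0 counts in low_force 109. Its low_force level of 2.41 ± 5.07 CPM (SD, n = 5) rests on low_force 092. It was not tested between the groups.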
